A study of Mus musculus with 13 samples.

How the data were processed

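RNA sequencing data were taken from 13 libraries of mouse cardiac muscle in 3 groups: sham surgery (n = 3), myocardial infarction (MI) with a control IgG (n = 5) and MI with the antibody FG-3149 (n = 5). Per the labels' protocols, RNA was extracted from left ventricle outside the ischaemic zone, 500 ng of total RNA entered a stranded mRNA library preparation, and all 13 libraries shared a flow cell with single reads of 75 bases. The groups were taken from the sample titles, which number the replicates within each group. The design text of the series speaks of animals, and the replicates were treated as separate animals on that basis.

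The authors deposited estimated counts per gene and per exon, keyed to RefSeq transcripts and Entrez gene numbers, and per the labels the genome build was mm10. The estimated counts were not normalized, and 79.4% of the gene values above 0 lay within 0.01 of a whole number. The deposited table of RPKM values gave reads scaled to transcript length and library total for 29163 transcripts of 22579 genes. The aligner, the counting tool, their versions, the strand setting and the treatment of reads with several matches were not given in the sources used here. The values of genes with near-identical copies (Myh6 and Myh7, Acot1 and Acot2, ribosomal protein genes with processed pseudogenes) and of overlapping or antisense genes are therefore uncertain to the extent that such reads were shared. Every library's counts correlated best with the RPKM column of the same name (lowest correlation across genes 0.93), although the libraries carried different run numbers in both tables.

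From the gene-level estimated counts, rounded to whole numbers, 379 entries that repeated the symbol of an entry with a higher mean count were left out. They held 0.0% of all reads. The remaining steps used R 4.3.3. Library totals ran from 10954922 to 17567238 estimated counts. Genes were kept by filterByExpr, which left 13434, and scaled by TMM factors in edgeR 4.0.16. All 13 libraries were fitted together by the quasi-likelihood method with robust dispersions and no covariate, since sham had only 3 libraries and the labels named no batch. The 3 contrasts between groups were tested with glmQLFTest, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. Levels are CPM, counts scaled to library totals, with TMM factors, given as mean ± SD over the libraries of a group. A prior count of 2 was added for log2 CPM, which was used for principal components and gene lists.

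A total of 43 gene lists (pathways, markers of cell types, and genes that follow sampling conditions) was fixed, of which 40 had at least 5 tested members. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, and again with a correlation estimated for each list. Ranges of camera p-values over refits are those at the preset correlation, over the alternatives for which camera was rerun. The fry test asked whether the members of a list moved, on balance, in the same direction. List p-values were adjusted over the 40 lists, and counts "adjusted over the list alone" come from adjusting the gene p-values within that list (counts within the list).

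The groups, tests, gene lists, processing alternatives and the rule for naming genes were chosen before the data were examined. The rule allowed, for each comparison, the 8 genes with the highest and the 8 with the lowest log2 fold change among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries of both groups, up to 4 members of each list with the smallest p, and 11 fixed genes of fibrosis and cardiac load. The genes named are a part of those the rule allowed, and this part was chosen after their values were seen. Some genes that the rule allowed are not reported here. Acta2, which is among the fixed genes, was listed at 0 in all 13 libraries and was not analysed here. This is unexpected in heart tissue and arose before the counts were deposited, so it is not evidence that the gene was silent. Of 36172 gene entries in the count table, 13593 had no transcript entry, and these held 0 reads. The table had 0 gene entries on the mitochondrial chromosome, so genes encoded there were not tested.

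The contrasts of MI with sham and of FG-3149 with IgG share the IgG libraries with opposite signs, so an opposed relation between them arises with no effect. This was measured in 50 simulated draws in which both infarcted groups had the same mean levels, and over the 10 ways to place 2 of the IgG libraries in the contrast with sham and the other 3 in the contrast with the antibody. The overlap of both infarcted groups against the shared sham libraries was likewise set beside 50 draws without effect. Other splits of the same libraries into groups of the same sizes were refitted, all 56 for each contrast with sham and 100 drawn for the antibody contrast.

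Alternatives were DESeq2 size factors, no expression filter, a filter of at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, a fit of only the groups compared, 1 surrogate variable from sva 3.50.0, the replicate number as a block, limma on log2(RPKM + 1) and log2(RPKM + 0.1), an adjusted p under 0.1, and leaving out each library in turn. Removal of each library's trend with GC content, removal of trends with GC content and transcript length, thinning to the smallest library total, and a block for the split of the infarcted libraries that called the most genes besides the real one (antibody contrast only) were added after the data were seen, as was leaving out IgG replicates 4 and 5 together, for their counts of atrial markers. GC content came from GENCODE M21 transcripts. It was matched through RefSeq accessions for 22101 genes and through symbols for 8876, while 4816 had no match, and 99.6% of the tested genes had a value.

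The fit was tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 genes changed. For FG-3149 against IgG it recovered 36% of 50 genes changed 1.25-fold, 76% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, with 7 false calls among 13322 tested genes. For IgG against sham the shares were 34%, 68%, 92% and 100% of 50 genes each, with 6 false calls among 13318 tested genes, and for FG-3149 against sham they were 36%, 70%, 90% and 100% of 50 genes each, with 4 false calls among 13309. No list was called in these simulations. Genes were drawn independently and changed with random signs, so this does not test camera on genes that change together. In a simulated GC trend for FG-3149 against IgG, the uncorrected fit called 2905 of 13328 tested genes and the corrected fit 158, of which 152 were among the 200 changed genes. Pairs of replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom of at least 3.52.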

Results

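Gene expression was measured in hearts of C57BL/6JO1aHsd mice, 8 to 10 weeks old at the start, in 3 groups. These were sham surgery (n = 3), MI with a control IgG (n = 5) and MI with FG-3149 (n = 5), an antibody against connective tissue growth factor (CTGF, encoded by Ctgf). FG-3149 and IgG were labelled with a dose of 10 mg/kg. The time point was labelled 1W+6W, an abbreviation that the labels do not spell out. Library totals were 12025880 to 14999813 estimated counts in sham, 13084735 to 17567238 with IgG and 10954922 to 12794823 with FG-3149. The totals of both infarcted groups did not overlap. The ribosomal precursor transcript Rn45s took 0.28% to 0.33% of counts in sham, 0.67% to 1.94% with IgG and 0.2% to 2.86% with FG-3149.

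The first principal component of log2 CPM held 46.8% of the variance. Its mean was -44.5 ± 2.7 (SD, n = 3) in sham, 16.9 ± 8.7 (SD, n = 5) with IgG and 9.9 ± 1.5 (SD, n = 5) with FG-3149. Sham differed from IgG and from FG-3149 with p = 0.0179 each (2-sided exact permutation test), the smallest p that 56 groupings can give. The difference between FG-3149 and IgG had p = 0.127 (2-sided exact permutation test of 252 groupings).

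**Figure D1:**
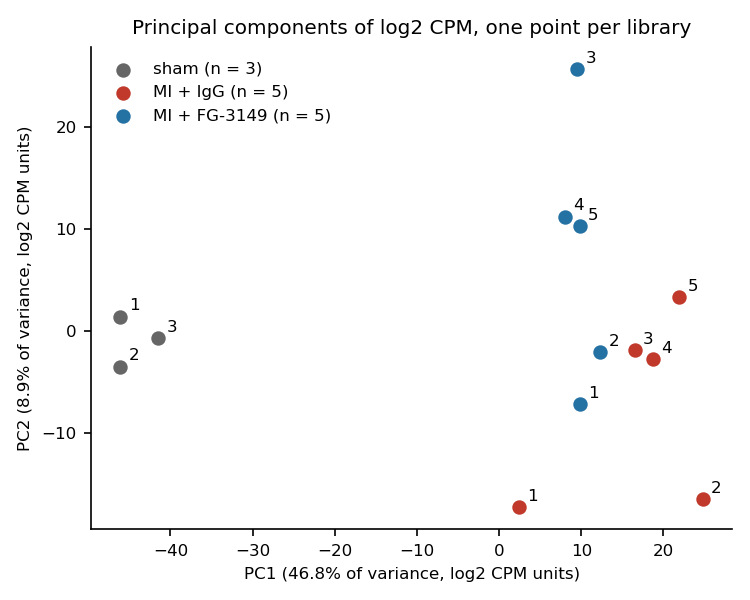
First and second principal components of log2 CPM over 13434 genes, in log2 CPM units, with a point per library and the replicate number beside it (grey, sham, n = 3; red, MI with IgG, n = 5; blue, MI with FG-3149, n = 5). The sham libraries lie between -46.1 and -41.5 on the first component and all 10 infarcted libraries between 2.4 and 24.8.

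The comparison of MI under control IgG with sham surgery asked which genes differed in ventricle outside the ischaemic zone after infarction. Ctgf, a matricellular protein of scarring tissue (Entrez gene 14219, mm10 chromosome 10, 24595442 to 24598682), rose 7.64-fold, from 42.5 ± 4.58 CPM (SD, n = 3) to 324.5 ± 74.3 CPM (SD, n = 5). Postn, a secreted protein of activated fibroblasts (Entrez gene 50706, chromosome 3, 54361107 to 54391041), rose 14.7-fold, from 37.1 ± 4.14 to 544 ± 175.5 CPM. Nppa, which encodes atrial natriuretic peptide (Entrez gene 230899, chromosome 4, 148000746 to 148002067), rose 22.1-fold to 2445 ± 720 CPM. Myh7, the fetal myosin heavy chain of the mouse ventricle (Entrez gene 140781, chromosome 14, 54970688 to 54994549), rose 13.6-fold to 3496 ± 758 CPM, while Myh6, the adult form, fell by 0.42 on the log2 scale (SE 0.07) to 22680 ± 1644 CPM.

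The log2 fold changes were 2.93 ± 0.25 (SE) for Ctgf, 3.87 ± 0.28 for Postn, 4.46 ± 0.42 for Nppa and 3.76 ± 0.28 for Myh7, and all 5 IgG libraries lay above all 3 sham libraries for each. The edgeR adjusted p was 4.39e-06 for Postn, 2.68e-05 for Nppa, 4.75e-06 for Myh7 and 0.000185 for Myh6. In all, 2393 genes were higher and 2136 lower of 13434 tested, 600 and 126 of them by more than 2-fold. An unadjusted p under 0.05 was reached by 5838 genes, against 672 expected by chance. The libraries of both groups did not overlap for 3938 of the 4529 called genes. These were called from the same libraries, so the 3.57% of genes that random groupings give is not a fair comparison. By camera, 22 of 40 gene lists were called, 19 higher and 3 lower, and 0 of them passed with an estimated correlation.

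Matrix genes were prominent among the higher lists. Of 20 activated fibroblast markers, 19 were higher, 0 lower and 1 did not pass, and 19 were higher adjusted over the list alone (camera adjusted p = 2.27e-16; adjusted p = 0.166 with an estimated correlation). Cilp, a matrix protein of cartilage, is on that list and rose 28.6-fold (log2 4.84 ± 0.28 SE). Of 30 non-collagen matrix proteins, 25 were higher, 0 lower and 5 did not pass, and 26 were higher adjusted over the list alone (camera adjusted p = 2.88e-18; adjusted p = 0.166 with an estimated correlation). The small leucine-rich proteoglycans Lum and Aspn rose 2.06-fold (log2 1.04 ± 0.08 SE) and 2.96-fold (log2 1.56 ± 0.10 SE). The microfibril component Mfap5 rose 6.02-fold (log2 2.59 ± 0.17 SE).

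Of 19 collagens, 15 were higher, 0 lower and 4 did not pass. Adjusted over the list alone, 16 were higher and 1 lower (camera adjusted p = 1.83e-09; adjusted p = 0.259 with an estimated correlation), with 0 lower without sham replicate 1, 2 or 3 or IgG replicate 3, 4 or 5. Col8a1, a short-chain collagen, rose 6.34-fold (log2 2.66 ± 0.18 SE). The fibrillar collagens Col1a1 and Col3a1 rose 2.36-fold (log2 1.24 ± 0.22 SE) and 2.02-fold (log2 1.01 ± 0.24 SE). In the IgG group, replicate 2 stood apart from the other 4 libraries for both, at 361 CPM against 194 to 227 for Col1a1 and at 871 CPM against 441 to 557 for Col3a1. Of 20 genes of collagen processing and crosslinking, 16 were higher, 0 lower and 4 did not pass, and 16 were higher adjusted over the list alone (camera adjusted p = 7.44e-09; adjusted p = 0.166 with an estimated correlation).

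Of 8 cartilage and bone markers, 6 were higher, 0 lower and 2 did not pass, and 7 were higher adjusted over the list alone (camera adjusted p = 1.80e-05; adjusted p = 0.166 with an estimated correlation). Comp, a cartilage matrix protein, rose from 0.609 ± 0.352 CPM in sham to 107 ± 53.1 CPM (log2 7.49 ± 0.89 SE), and IgG replicate 2 stood apart at 201 CPM. The collagen-binding proteoglycan Fmod rose from 0.604 ± 0.0943 to 63.9 ± 25.2 CPM (log2 6.70 ± 0.78 SE). With sham levels this low the folds moved with the scale, to 5.08 for Comp and 4.21 for Fmod on log2(RPKM + 1), which understates changes of low genes, and to 6.11 for Fmod on log2(RPKM + 0.1). Of 16 fibroblast markers, 11 were higher, 1 lower and 4 did not pass. When adjusted over the list alone, 11 were higher and 2 lower (camera adjusted p = 9.82e-05; adjusted p = 0.243 with an estimated correlation). Without IgG replicate 1, 3 were lower, and without sham replicate 2 or 3, 1 was lower adjusted over the list alone. Dcn and Pi16, expressed in cardiac fibroblasts, rose 1.62-fold (log2 0.69 ± 0.08 SE) and 3.60-fold (log2 1.85 ± 0.13 SE). The fibroblast marker Scara5 fell by 0.79 on the log2 scale (SE 0.10).

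Of 26 TGF-beta signalling and target genes, 18 were higher, 1 lower and 7 did not pass. Adjusted over the list alone, 18 were higher and 3 lower (camera adjusted p = 3.73e-06; adjusted p = 0.166 with an estimated correlation). In both counts 0 were lower without sham replicate 1, as over all genes without sham replicate 3 or IgG replicate 3 or 5. The ligand Tgfb1 rose 1.37-fold (log2 0.46 ± 0.10 SE) and the oxidase Nox4 rose 12.9-fold (log2 3.68 ± 0.35 SE). Of 17 genes of the CCN family and YAP/TEAD targets, 7 were higher, 1 lower and 9 did not pass, with the same counts of 7 and 1 adjusted over the list alone (camera adjusted p = 0.00336; adjusted p = 0.307 with an estimated correlation). Of 21 matrix proteases and inhibitors, 9 were higher, 2 lower and 10 did not pass. When adjusted over the list alone, 11 were higher and 3 lower (camera adjusted p = 0.0105; adjusted p = 0.417 with an estimated correlation). Over all genes, 4 proteases and inhibitors were lower without IgG replicate 1 and 1 without sham replicate 1 or 3 or IgG replicate 3, 4 or 5. Within the list, 7 were higher and 1 lower without sham replicate 1 or 3, and 5 were lower without IgG replicate 2. Timp1, a metalloproteinase inhibitor, rose 24.0-fold, from 0.642 ± 0.162 to 15.4 ± 3.93 CPM (log2 4.58 ± 0.34 SE). On log2(RPKM + 1) the fold changes of Nox4 and Timp1 were 1.84 and 3.40.

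Genes of fatty acid oxidation and oxidative phosphorylation moved the other way. Of 34 genes of fatty acid oxidation, 0 were higher, 29 lower and 5 did not pass, and 30 were lower adjusted over the list alone (camera adjusted p = 8.94e-16; adjusted p = 0.166 with an estimated correlation). Hadha, of the mitochondrial trifunctional protein, fell by 0.60 on the log2 scale (SE 0.06), and Acaa2, a thiolase, fell by 0.82 (SE 0.08). Of 50 genes of oxidative phosphorylation, 0 were higher, 42 lower and 8 did not pass, and 47 were lower adjusted over the list alone (camera adjusted p = 8.16e-16; adjusted p = 0.301 with an estimated correlation). Sdha of complex II fell by 0.44 (SE 0.06) and Cox7a1 of complex IV by 0.51 (SE 0.07) on the log2 scale. Acot1, an acyl-CoA thioesterase, had 15.1 ± 1.17 CPM in sham and 2.60 ± 1.65 CPM with IgG (log2 fold change -2.57 ± 0.28 SE). IgG replicate 1 stood apart for Acot1, at 5.52 CPM against 1.49 to 2.14. Of 28 genes of glycolysis and glucose use, 6 were higher, 12 lower and 10 did not pass, with 7 higher and 13 lower adjusted over the list alone. That list was not called (median log2 fold change -0.08; camera adjusted p = 0.226; adjusted p = 0.727 with an estimated correlation). With a library left out, 3 to 7 were higher and 8 to 13 lower, with 3 higher without sham replicate 1 or 3. Within the list, 4 were higher without sham replicate 2 or 3, as without IgG replicates 4 and 5 together.

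Of 17 hypertrophy and fetal cardiac genes, 13 were higher, 1 lower and 3 did not pass. Adjusted over the list alone, 14 were higher and 1 lower (camera adjusted p = 4.17e-09; adjusted p = 0.166 with an estimated correlation), and over all genes 0 were lower without sham replicate 3. Ankrd1, a stress-responsive sarcomere protein, rose 7.95-fold (log2 2.99 ± 0.20 SE), with IgG replicate 1 apart at 3090 CPM against 4470 to 4910. Nppb, which encodes brain natriuretic peptide, rose 3.35-fold (log2 1.75 ± 0.32 SE). Of 34 genes for ion channels and calcium handling, 2 were higher, 14 lower and 18 did not pass. When adjusted over the list alone, 3 were higher and 14 lower (camera adjusted p = 0.00315; adjusted p = 0.242 with an estimated correlation). In both counts 1 was higher without sham replicate 1, 2 or 3, as over all genes without IgG replicate 4 or 5. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 0.51 (SE 0.06) and its inhibitor Pln by 0.63 (SE 0.08) on the log2 scale. The potassium channel subunit Kcnv2 fell by 1.92 (SE 0.26), with IgG replicate 1 apart at 10.6 CPM against 4.34 to 5.45, and had -1.33 on log2(RPKM + 1).

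Cell type markers other than those of fibroblasts went several ways. Of 14 cardiomyocyte markers, 2 were higher, 5 lower and 7 did not pass, with the same counts of 2 and 5 adjusted over the list alone. Their median log2 fold change was 0.00, their mean 0.20 and the camera direction down (adjusted p = 0.478; adjusted p = 0.727 with an estimated correlation). Of 19 macrophage markers, 12 were higher, 0 lower and 7 did not pass, and 15 were higher adjusted over the list alone (camera adjusted p = 2.23e-05; adjusted p = 0.307 with an estimated correlation). C1qb rose 2.14-fold (log2 1.10 ± 0.17 SE) and Lgals3 6.23-fold (log2 2.64 ± 0.41 SE). Of 13 endothelial markers, 1 was higher, 2 lower and 10 did not pass, with 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.563; adjusted p = 0.819 with an estimated correlation). Of these, 0 were higher without sham replicate 1 or 3 or IgG replicate 3 or 5, and 1 was lower without sham replicate 2. The VEGF receptor gene Kdr fell by 0.59 on the log2 scale (SE 0.10).

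Of 16 complement genes, 13 were higher, 0 lower and 3 did not pass, and 15 were higher adjusted over the list alone (camera adjusted p = 1.35e-08; adjusted p = 0.166 with an estimated correlation). Of 37 interferon response genes, 13 were higher, 1 lower and 23 did not pass. Adjusted over the list alone, 14 were higher and 1 lower (camera adjusted p = 0.000528; adjusted p = 0.417 with an estimated correlation), and without sham replicate 1 the list had 9 higher and 0 lower in both counts, as it had 0 lower without sham replicate 3. Of 30 cytokines and chemokines, 9 were higher, 2 lower and 19 did not pass. When adjusted over the list alone, 10 were higher and 2 lower (camera adjusted p = 0.00984; adjusted p = 0.166 with an estimated correlation), and the chemokine Cxcl12 fell by 0.56 on the log2 scale (SE 0.09). Of 37 cell cycle and mitosis genes, 27 were higher, 2 lower and 8 did not pass. Adjusted over the list alone, 29 were higher and 2 lower (camera adjusted p = 4.58e-09; adjusted p = 0.261 with an estimated correlation), and over all genes 1 was lower without sham replicate 1 or 3 or IgG replicate 3. The topoisomerase Top2a rose 2.35-fold (log2 1.23 ± 0.18 SE). The D-type cyclin Ccnd2 rose 1.75-fold (log2 0.81 ± 0.10 SE), with IgG replicate 1 apart at 244 CPM against 333 to 348.

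Lists of genes that follow tissue handling or time of day were counted as well, where 33.7% of all tested genes were called. Of 21 immediate early genes, 7 were higher, 0 lower and 14 did not pass, and 7 were higher adjusted over the list alone (camera adjusted p = 0.0379; adjusted p = 0.602 with an estimated correlation). The list was no longer called without sham replicate 1 or 3 (camera adjusted p = 0.142 and 0.0831), without IgG replicate 1 or 2 (0.0631 and 0.0618) or with the GC trend removed (0.0526), over a range in the refits of 0.00185 to 0.142, and 1 member was lower without sham replicate 3. Of 40 ribosomal protein genes, 9 were higher, 0 lower and 31 did not pass, and 7 were higher adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.727 with an estimated correlation). This call was lost without IgG replicate 1, 2 or 3 (camera adjusted p = 0.0905, 0.0509 and 0.0565) and with the GC trend removed (0.095, with 4 higher and 1 lower), over a range in the refits of 0.0003 to 0.095. The number higher was 5, 4 and 4 without sham replicates 1, 2 and 3. Within the list it was 1, 1 and 2 without these, 3 without IgG replicate 2 or 3, 12 without IgG replicate 5 and 11 without IgG replicates 4 and 5 together. Of 16 clock genes, 7 were higher, 4 lower and 5 did not pass, with 9 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.104; adjusted p = 0.417 with an estimated correlation). The counts were 3, 6 and 4 higher without sham replicates 1, 2 and 3 and 4, 4 and 6 higher without IgG replicates 3, 4 and 5, each with 1 lower, and 3 higher and 1 lower without IgG replicates 4 and 5 together. Within the list, 4 were higher and 1 lower without sham replicate 1 or 3.

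The clock output Dbp rose 6.39-fold (log2 2.68 ± 0.51 SE) to 93.8 ± 42.4 CPM, and the clock gene Per2 rose 6.48-fold (log2 2.70 ± 0.59 SE) to 36.7 ± 16.1 CPM, with 1.83 on log2(RPKM + 1). Arntl, a core clock transcription factor gene, fell by 2.02 on the log2 scale (SE 0.65), from 33.7 ± 3.27 to 8.29 ± 6.67 CPM (edgeR adjusted p = 0.0366, with a range over the alternatives of 0.00459 to 0.125). Its call ended without sham replicate 1, 2 or 3 (adjusted p = 0.0985, 0.0816 and 0.0745), without IgG replicate 3, 4 or 5 (adjusted p = 0.0757, 0.0718 and 0.0643) or both of the last (adjusted p = 0.125), and with 1 surrogate variable (adjusted p = 0.11), and limma voom gave -2.65. In the IgG group, Arntl was at 15.8 and 15.3 CPM in replicates 1 and 2 and at 4.82, 3.12 and 2.46 CPM in replicates 3, 4 and 5. With FG-3149 it was at 13.85, 15 and 18.5 CPM in replicates 1, 2 and 3 and at 2.98 and 2.77 CPM in replicates 4 and 5. Over the 10 infarcted libraries, Dbp ran from 58.7 CPM in IgG replicate 1 to 173 CPM in FG-3149 replicate 4, and Per2 from 9.83 CPM in FG-3149 replicate 3 to 60.3 CPM in IgG replicate 5.

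**Figure D2:**
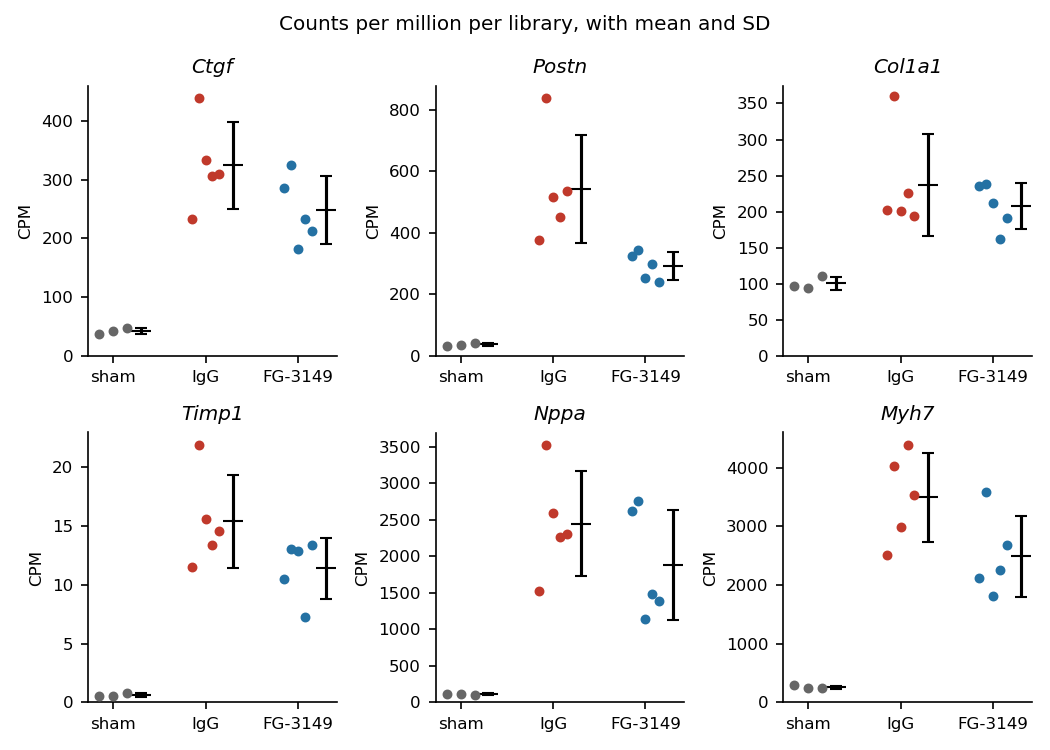
CPM (linear axes from 0) of Ctgf, Postn, Col1a1, Timp1, Nppa and Myh7, with a point per library and the mean and SD at the right of each group (sham, n = 3; MI with IgG, n = 5; MI with FG-3149, n = 5). Ctgf averaged 42.5 CPM in sham, 324.5 CPM with IgG and 248 CPM with FG-3149, and Postn averaged 37.1, 544 and 292 CPM.

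The comparison of FG-3149 with control IgG among infarcted hearts asked what differed under the CTGF antibody. The transcription factor gene Jund (Entrez gene 16478, mm10 chromosome 8, 70697739 to 70700616) rose 1.78-fold, from 53.2 ± 5.95 to 94.7 ± 10.5 CPM (SD, n = 5 each). The cardiac transcription factor genes Nkx2-5 (Entrez gene 18091, chromosome 17, 26838665 to 26841565) and Hand2 rose 1.63-fold and 1.39-fold. Cox5a, a subunit of cytochrome c oxidase, rose 1.29-fold, from 658 ± 42.0 to 848 ± 77.7 CPM. The matrix proteoglycan gene Lum (Entrez gene 17022, chromosome 10, 97565501 to 97572703) fell by 0.41 on the log2 scale (SE 0.07), from 127 ± 12.4 to 95.9 ± 2.96 CPM. Aspn, another such gene (Entrez gene 66695, chromosome 13, 49544443 to 49567562), fell by 0.47 (SE 0.08), from 81.3 ± 10.55 to 58.6 ± 3.55 CPM, and both had been higher after infarction than in sham.

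The edgeR adjusted p was 0.000173 for Jund (log2 fold change 0.83 ± 0.08 SE), 0.00166 for Nkx2-5 (0.71 ± 0.09) and 0.0048 for Hand2 (0.47 ± 0.08). It was 0.00417 for Cox5a (0.37 ± 0.06), 0.00393 for Lum and 0.00767 for Aspn. For each of these 6 genes the 5 libraries of both groups did not overlap. With FG-3149, 123 genes were higher and 21 lower of 13434 tested, 13 and 2 of them by more than 2-fold. An unadjusted p under 0.05 was reached by 1849 genes, against 672 expected by chance. The libraries of both groups did not overlap for 123 of the 144 called genes. These were called from the same libraries, so the 0.79% of genes that random groupings give is not a fair comparison. On log2(RPKM + 1), limma called 77 genes higher and 28 lower, and on log2(RPKM + 0.1) it called 73 higher and 25 lower.

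**Figure D3:**
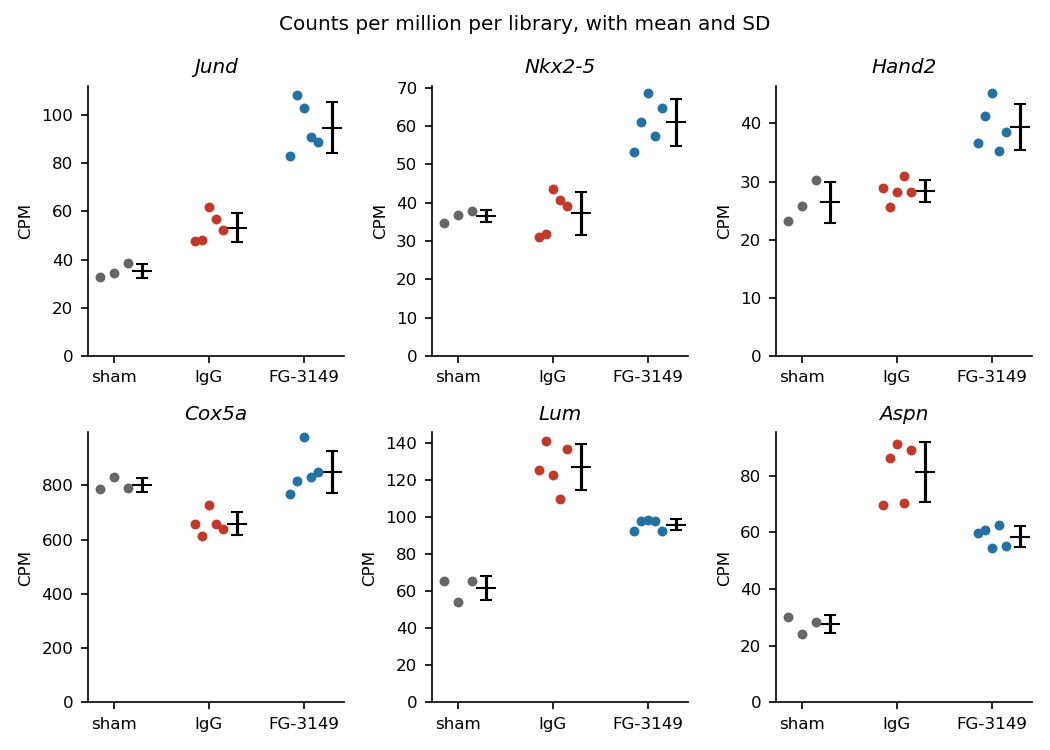
CPM (linear axes from 0) of Jund, Nkx2-5, Hand2, Cox5a, Lum and Aspn, with a point per library and the mean and SD at the right of each group (sham, n = 3; MI with IgG, n = 5; MI with FG-3149, n = 5). Jund averaged 53.2 CPM with IgG and 94.7 CPM with FG-3149, and Lum averaged 127 and 95.9 CPM.

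Several of the higher genes had GC-rich transcripts. Scand1 rose 3.81-fold (log2 1.93 ± 0.26 SE; edgeR adjusted p = 0.00534), with FG-3149 replicate 1 apart at 14.8 CPM against 24.9 to 28.2. The nuclear receptor gene Nr2f6 rose 1.75-fold (log2 0.81 ± 0.10 SE; edgeR adjusted p = 0.00106). The GC content was 68.4% for Scand1, 67.3% for Nr2f6, 67.2% for Jund and 67.1% for Nkx2-5. The median was 50.4% over all tested genes and 56.8% over the genes that were higher. Across genes, which are not independent replicates, each library's deviation from the mean log2 CPM was rank-correlated with GC content. This correlation averaged 0.16 ± 0.03 (SD, n = 5) with FG-3149 and 0.00 ± 0.13 (SD, n = 5) with IgG (p = 0.0238, 2-sided exact permutation test of 252 groupings).

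With each library's GC trend removed, the log2 fold changes were 0.50 ± 0.06 (SE) for Jund, 0.38 ± 0.07 for Nkx2-5, 0.47 ± 0.07 for Nr2f6 and 1.56 ± 0.21 for Scand1, all still called. Over all alternatives, the adjusted p of these reached at most 0.0018, 0.00849, 0.00694 and 0.0381. The pacemaker channel gene Hcn2, the junctophilin gene Jph2 and the growth factor gene Vegfb rose 1.56-, 1.23- and 1.21-fold (log2 0.64 ± 0.10, 0.29 ± 0.04 and 0.28 ± 0.05 SE). Without the GC trend their log2 fold changes were 0.37 ± 0.09, 0.16 ± 0.05 and 0.13 ± 0.05 (SE). They then no longer passed (edgeR adjusted p = 0.0642, 0.116 and 0.281, the highest over all alternatives, from lowest values of 2.15e-06, 1.47e-09 and 8.16e-05), nor with GC and length trends removed (adjusted p = 0.0602, 0.0706 and 0.258). Vegfb also did not pass without IgG replicates 4 and 5 together (adjusted p = 0.0855).

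By camera, 14 of 40 gene lists were called, 6 higher and 8 lower, and 0 of them passed with an estimated correlation. Leaving out each library in turn kept 6 of the 14 calls and ended 8. Of 50 genes of oxidative phosphorylation, 5 were higher, 0 lower and 45 did not pass, and 11 were higher adjusted over the list alone (camera adjusted p = 8.50e-13; adjusted p = 0.681 with an estimated correlation). The number higher was 1, 3 and 2 without IgG replicates 2, 4 and 5 and 2, 1 and 1 without FG-3149 replicates 3, 4 and 5, while the list stayed called. Within the list it was 17, 7, 17, 6 and 7 without IgG replicates 1, 2, 3, 4 and 5 and 23 and 6 without FG-3149 replicates 2 and 3, and without IgG replicates 4 and 5 together it was 1 over all genes and 6 within the list. Cox5a passed under every alternative. Of 34 genes of fatty acid oxidation, 1 was higher (Acot2), 0 lower and 33 did not pass, and 2 were higher adjusted over the list alone (camera adjusted p = 7.70e-08; adjusted p = 0.681 with an estimated correlation). Acot2 had a log2 fold change of 0.47 (edgeR adjusted p = 0.0404, with a range over the alternatives of 0.000319 to 0.156). It was not called in 14 of 26 alternatives. Among these were no filter (adjusted p = 0.0546), only both groups (0.081), the replicate number as a block (0.07) and leaving out FG-3149 replicate 2 (0.0676). The number higher was 7 without IgG replicate 1 and 0 without IgG replicate 2, 3, 4 or 5, without FG-3149 replicate 3, 4 or 5 and with the GC trend removed, and the list stayed called. Within the list it was 17 without IgG replicate 1, 7 without FG-3149 replicate 2 and 1 without IgG replicate 2 or 5 or FG-3149 replicate 3, and in both counts 0 without IgG replicates 4 and 5 together. Of 34 genes for ion channels and calcium handling, 3 were higher, 0 lower and 31 did not pass, and 3 were higher adjusted over the list alone (camera adjusted p = 0.00496; adjusted p = 0.681 with an estimated correlation). With the GC trend removed 1 was higher, and without FG-3149 replicate 5 the list was not called (camera adjusted p = 0.0675, the highest over the refits, from a lowest of 0.00087), and 8 were higher within the list without IgG replicate 1. Of 42 cardiac development regulators, 2 were higher, 0 lower and 40 did not pass, and 5 were higher adjusted over the list alone (camera adjusted p = 0.00294; adjusted p = 0.681 with an estimated correlation), against 3, 3 and 2 without IgG replicates 2, 3 and 5 and 2 without FG-3149 replicate 3 or IgG replicates 4 and 5 together. Glycolysis and glucose use was called higher with 0 of 28 members passing and 2 higher adjusted over the list alone (camera adjusted p = 0.00998; adjusted p = 0.681 with an estimated correlation). It was not called without FG-3149 replicate 4 or 5 (camera adjusted p = 0.0597 and 0.0831, with a lowest value over the refits of 0.000941). Without IgG replicate 1, 2 of its genes passed, and within the list 4 were higher without FG-3149 replicate 1 or 2 and 0 without IgG replicate 2, 3 or 5, FG-3149 replicate 3, 4 or 5 or IgG replicates 4 and 5 together. Cardiomyocyte markers were called higher with 0 of 14 passing, also adjusted over the list alone (camera adjusted p = 0.0485; adjusted p = 0.681 with an estimated correlation). They were not called without IgG replicate 2 or 4 (camera adjusted p = 0.195 and 0.109), FG-3149 replicate 3, 4 or 5 (0.0568, 0.099 and 0.146) or IgG replicates 4 and 5 together (0.063), with a lowest value over the refits of 0.0191. Without FG-3149 replicate 1, 1 member passed, as within the list without IgG replicate 3 or FG-3149 replicate 2.

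Of 30 non-collagen matrix proteins, 0 were higher, 3 lower and 27 did not pass, and 9 were lower adjusted over the list alone (camera adjusted p = 7.70e-08; adjusted p = 0.681 with an estimated correlation). The members that passed were Lum, Aspn and Mfap5, and 6 passed without IgG replicate 1, while 5 were lower within the list without FG-3149 replicate 4. Mfap5 fell by 0.63 on the log2 scale (SE 0.13; edgeR adjusted p = 0.0349, with a range over the alternatives of 6.10e-05 to 0.107). Its call ended without IgG replicate 3, 4 or 5 (adjusted p = 0.0684, 0.0553 and 0.0656), without IgG replicates 4 and 5 together (adjusted p = 0.101) and without FG-3149 replicate 2, 3, 4 or 5 (adjusted p = 0.0559, 0.107, 0.0929 and 0.0844). It also ended with no filter (adjusted p = 0.0522), in a fit of only both groups (0.068), with 1 surrogate variable (0.0508) and with the replicate number as a block (0.0767). With the GC trend removed the log2 fold change was -0.62 ± 0.13 (SE), about as before, and the adjusted p 0.0519, and it was 0.0602 with GC and length trends removed.

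Of 20 activated fibroblast markers, 0 were higher, 1 lower and 19 did not pass, and 4 were lower adjusted over the list alone (camera adjusted p = 0.000215; adjusted p = 0.681 with an estimated correlation). The member that passed was Cthrc1, a secreted protein of activated fibroblasts (log2 fold change -1.17 ± 0.28 SE; edgeR adjusted p = 0.0491, with a range over the alternatives of 0.0114 to 0.131). It was not called without IgG replicate 2, 4 or 5 (adjusted p = 0.131, 0.0693 and 0.068) or 4 and 5 together (adjusted p = 0.0855), without FG-3149 replicate 2, 3, 4 or 5 (adjusted p = 0.0635, 0.13, 0.128 and 0.101) or with the GC trend removed (adjusted p = 0.0621), which left 0 members lower. The log2 fold change was then -1.15 ± 0.28 (SE), about as before, and the adjusted p before the removal had been just under 0.05. Cthrc1 was also not called with a CPM filter (0.0505), limma voom (0.0737), only both groups (0.0923), 1 surrogate variable (0.0523), log2(RPKM + 1) (0.0536), log2(RPKM + 0.1) (0.0597) or GC and length trends removed (0.0708). IgG replicate 2 stood apart for Cthrc1, at 7.32 CPM against 2.98 to 3.61, and without it the log2 fold change was -0.84. Without IgG replicate 1, 3 members were lower, and within the list 7 without FG-3149 replicate 1 and 2 without IgG replicate 2 or 4 or FG-3149 replicate 3 or 4. Collagens were called lower with 0 of 19 passing and 1 lower adjusted over the list alone (camera adjusted p = 0.00294; adjusted p = 0.681 with an estimated correlation). Collagen processing and crosslinking was called lower with 0 of 20 passing, also adjusted over the list alone (camera adjusted p = 0.00138; adjusted p = 0.681 with an estimated correlation). Without IgG replicate 2 neither was called (camera adjusted p = 0.231 and 0.0891, with lowest values over the refits of 7.52e-06 and 5.32e-05), and without IgG replicate 1, 1 member of each passed. Within the list, the collagens had 1 lower without IgG replicate 1 and 0 without each other library, and collagen processing had 4 lower without IgG replicate 1.

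Hypertrophy and fetal cardiac genes were called lower with 0 of 17 passing and 1 lower adjusted over the list alone (camera adjusted p = 0.0258; adjusted p = 0.681 with an estimated correlation). They were not called without IgG replicate 2 or 4 (camera adjusted p = 0.101 and 0.0594) or FG-3149 replicate 3 or 5 (0.131 and 0.0831), over a range in the refits of 0.00167 to 0.168. Without IgG replicate 1, 2 genes of the list passed, as did 1 without FG-3149 replicate 1. Within the list, 5 were lower without IgG replicate 1, 4 without FG-3149 replicate 2 and 0 without IgG replicate 2 or 4 or FG-3149 replicate 5, and 1 was higher without FG-3149 replicate 3. The list shares Nppa, Myl4 and Myl7 with the atrial cardiomyocyte markers. Myl4, an atrial myosin light chain gene, was at 21.5 and 30.7 CPM in IgG replicates 4 and 5 and at 1.91 to 3.06 CPM in the other 8 infarcted libraries (log2 fold change -2.19 ± 0.84 SE; edgeR adjusted p = 0.287, with a range over the alternatives of 0.0752 to 0.988). Of the 13 markers on the atrial list, 5 lay above the other 8 infarcted libraries in both of these and 8 did not, and the markers besides Myl4 are named after their values were seen. Myl7, an atrial myosin light chain gene as well, had 142 and 178 estimated counts against 0 to 3, Sln, which encodes the calcium pump regulator sarcolipin, 9 and 30 against 0, and Cpne5 35 and 31 against 0 to 4. Myl7 and Sln did not pass the expression filter and were not tested. Pam lay just above, at 1244 and 1268 CPM against 938 to 1234. Nppa was at 2268 and 2306 CPM, within the range of 1136 to 3524 CPM of the other 8, and Bmp10, Stard10, Dkk3, Tbx5, Kcnj3 and Nr2f1 lay within theirs as well. Nr2f2 lay above in replicate 4 alone, at 11.3 CPM against 8.13 to 10.6. Of 10 tested atrial markers 0 passed, also adjusted over the list alone (median log2 fold change -0.04, mean -0.44; camera adjusted p = 0.901; adjusted p = 0.931 with an estimated correlation), and within the list 2 were higher and 2 lower without IgG replicate 1. Without IgG replicates 4 and 5 together, the hypertrophy list was not called (camera adjusted p = 0.168), with 0 lower within the list, and Myl4 had a log2 fold change of -0.02, against -1.51 without replicate 5 alone.

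Cell cycle and mitosis was called lower with 0 of 37 passing, also adjusted over the list alone (camera adjusted p = 0.0006; adjusted p = 0.681 with an estimated correlation). Without IgG replicate 1, 1 member passed and 8 were lower adjusted over the list alone, and without IgG replicates 4 and 5 together the list was not called (camera adjusted p = 0.225, the highest over the refits, from a lowest of 2.19e-08). Interferon response was called lower with 1 of 37 lower and 36 not passing, and 1 lower adjusted over the list alone (camera adjusted p = 0.0258; adjusted p = 0.681 with an estimated correlation). That list was not called without IgG replicate 1 or 2 (camera adjusted p = 0.27 and 0.0537) or FG-3149 replicate 5 (0.469), with a lowest value over the refits of 0.00173. Within the list, 3 were lower without IgG replicate 3 and 0 without IgG replicate 2 or 4, both 4 and 5 or FG-3149 replicate 5. Its lower member was Ifit2 (log2 fold change -0.28 ± 0.06 SE; edgeR adjusted p = 0.0443, with a range over the alternatives of 0.0158 to 0.188). Ifit2 was not called without IgG replicate 1, 2, 4 or 5 (adjusted p = 0.0544, 0.121, 0.101 and 0.0868) or 4 and 5 together (adjusted p = 0.188), without FG-3149 replicate 1, 3, 4 or 5 (adjusted p = 0.0628, 0.0916, 0.104 and 0.108) or with the GC trend removed (adjusted p = 0.0977), which left 0 members lower, and 2 were lower without IgG replicate 3. The log2 fold change without the GC trend was -0.24 ± 0.06 (SE), a little smaller with an error as large. Ifit2 was also not called with limma voom (0.0576), only both groups (0.081), log2(RPKM + 1) (0.0592), log2(RPKM + 0.1) (0.063), GC and length trends removed (0.0894) or counts thinned to 1 depth (0.1).

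Endothelial markers were called lower with 0 of 13 passing, also adjusted over the list alone (camera adjusted p = 0.0199; adjusted p = 0.681 with an estimated correlation). They were not called without IgG replicate 1 or 2 (camera adjusted p = 0.0696 and 0.142) or FG-3149 replicate 2 or 5 (0.0537 and 0.0502), with a lowest value over the refits of 5.67e-05, and 1 member passed without FG-3149 replicate 4. Within the list, 6 were lower without IgG replicate 5 or both 4 and 5, 2 without FG-3149 replicate 4 and 2 without FG-3149 replicate 5. Of 16 fibroblast markers, 1 was lower (Lum) and 15 did not pass, and 4 were lower adjusted over the list alone. That list was not called (camera adjusted p = 0.0709; adjusted p = 0.681 with an estimated correlation) but was without IgG replicate 4 or 5 (0.0289 and 0.0282) and FG-3149 replicate 1 or 3 (0.0383 and 0.0369) and with the split of the infarcted libraries as a block (0.00695) and without IgG replicates 4 and 5 together (0.00569), with a highest value over the refits of 0.427, and 2 members were lower without IgG replicate 1 or 4 or both 4 and 5. Within the list, 2 were lower without IgG replicate 2, 3 or 5, both 4 and 5 or FG-3149 replicate 1, 3 or 4. Of 16 clock genes and 19 macrophage markers 0 passed, also adjusted over the list alone (camera adjusted p = 0.705 and 0.487; adjusted p = 0.931 with an estimated correlation for both). The macrophage list was called without IgG replicate 1 or FG-3149 replicate 3 (camera adjusted p = 0.0112 and 0.0127, with a highest value over the refits of 0.971).

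Ctgf itself did not pass, with 324.5 ± 74.3 CPM with IgG and 248 ± 57.2 CPM with FG-3149 (log2 fold change -0.39 ± 0.19 SE; edgeR adjusted p = 0.394). Postn had a log2 fold change of -0.90 ± 0.20 SE (edgeR adjusted p = 0.0688, with a range over the alternatives of 0.00296 to 0.164). It passed without IgG replicate 1 (adjusted p = 0.0274), with DESeq2 (adjusted p = 0.00296) and with a split of the infarcted libraries across both antibodies as a block (adjusted p = 0.0489). Col1a1, Col3a1 and Timp1 had log2 fold changes of -0.19 ± 0.18, -0.18 ± 0.20 and -0.43 ± 0.18 SE (edgeR adjusted p = 0.701, 0.751 and 0.291). Without IgG replicate 2, those of Col1a1 and Col3a1 were 0.01 and 0.02. Nppa, Nppb and Myh7 had log2 fold changes of -0.38 ± 0.29, -0.28 ± 0.26 and -0.49 ± 0.20 SE (edgeR adjusted p = 0.62, 0.702 and 0.319). Myh6 had 0.13 ± 0.06 SE (edgeR adjusted p = 0.35) and Tgfb1 0.05 ± 0.09 SE (edgeR adjusted p = 0.846). Tgfb1 was at -0.10 with the GC trend removed and at -0.02 without FG-3149 replicate 3.

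The number of called genes was 68 without IgG replicate 2, 90 without IgG replicate 5, 76, 74 and 84 without FG-3149 replicates 3, 4 and 5, and 83 in a fit of only the infarcted libraries. It was 271 (175 higher and 96 lower) without IgG replicate 1 and 278 (220 higher and 58 lower) with DESeq2, and 70 (58 higher and 12 lower, 53 of them among the 144) without IgG replicates 4 and 5 together, a setting chosen after the data were seen. The number of called lists was 8 without IgG replicate 2 or FG-3149 replicate 5 and 0 by fry. The split of the infarcted libraries that set IgG replicates 1 and 2 and FG-3149 replicates 1, 2 and 3 against the rest called 151 genes. With that split as a block, 283 genes were called for the antibody (206 higher and 77 lower), and all 144 were among them.

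**Figure D4:**
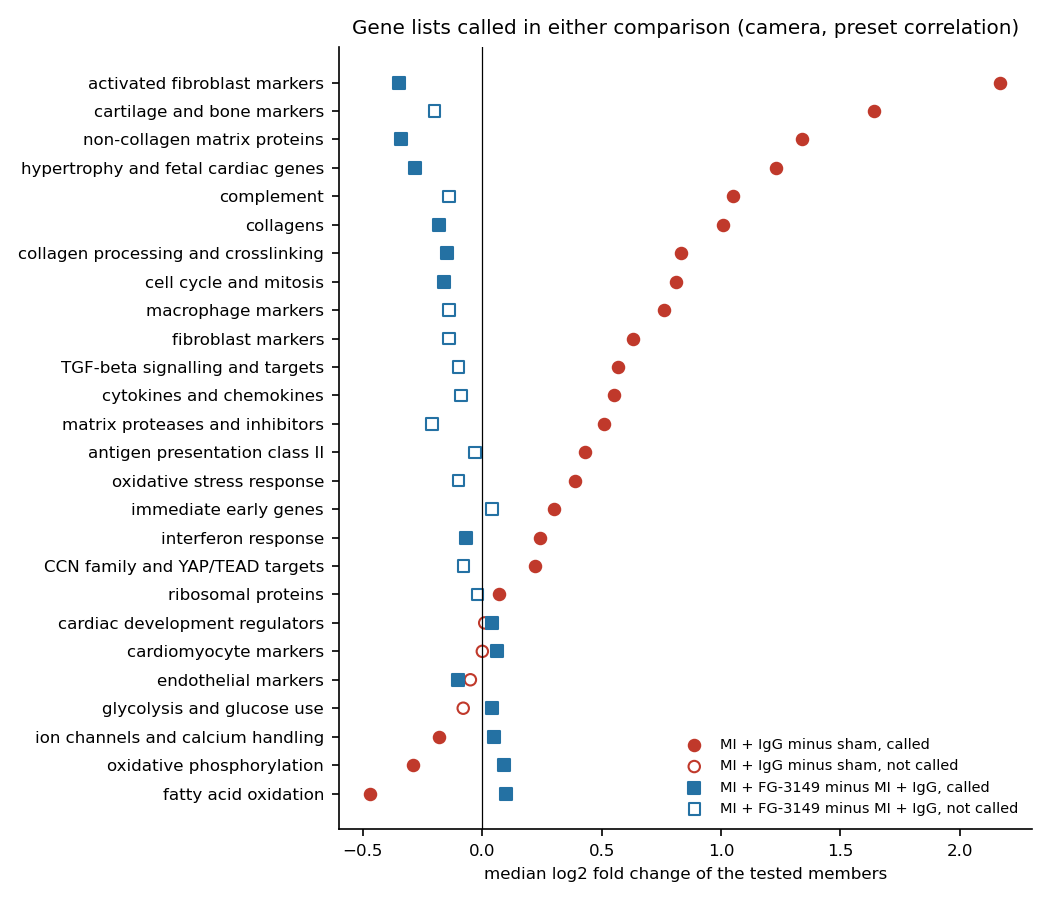
Median log2 fold change over the tested members of each gene list that camera called (preset correlation of 0.01) in the comparison of IgG with sham (red circles) or of FG-3149 with IgG (blue squares). Filled symbols mark called lists and open symbols lists that were not called, with activated fibroblast markers at 2.17 and -0.35 and fatty acid oxidation at -0.47 and 0.10; 0 lists were called with an estimated correlation.

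The comparison of FG-3149 with sham asked what differed from uninfarcted hearts under the CTGF antibody. Ctgf rose 5.84-fold to 248 ± 57.2 CPM (SD, n = 5; log2 2.55 ± 0.25 SE), and Postn rose 7.87-fold to 292 ± 45.2 CPM (log2 2.98 ± 0.27 SE). Nppa rose 16.9-fold (log2 4.08 ± 0.41 SE), Myh7 9.66-fold (log2 3.27 ± 0.27 SE) and Nppb 2.77-fold (log2 1.47 ± 0.32 SE). The matrix genes Comp and Fmod rose by 7.32 ± 0.89 and 6.14 ± 0.81 (SE) on the log2 scale. Ltbp2, which binds fibrillin microfibrils, and Col12a1, a fibril-associated collagen, rose by 4.97 ± 0.56 and 5.33 ± 0.72 (SE). The metalloproteinase inhibitor Timp1 rose 17.7-fold (log2 4.15 ± 0.35 SE). On log2(RPKM + 1), which understates changes of low genes, Comp, Fmod, Ltbp2, Col12a1 and Timp1 had 4.86, 3.61, 3.11, 1.41 and 2.96, and on log2(RPKM + 0.1) Fmod and Col12a1 had 5.47 and 3.68. Col12a1, at 0.0677 to 1.08 CPM in sham, had 4.74 without sham replicate 2 and 6.19 without sham replicate 3, and all 5 genes stayed called.

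Among the lower genes, Ano10, of a family of ion channels and scramblases, fell by 1.81 (SE 0.13) on the log2 scale. The galectin gene Lgals4 fell by 1.61 (SE 0.16) and the carboxylesterase gene Ces1d by 1.56 (SE 0.24). In this comparison 2098 genes were higher and 1861 lower of 13434 tested (edgeR), 473 and 98 of them by more than 2-fold. The edgeR adjusted p was 5.52e-05 for Ctgf, 3.97e-05 for Postn and 8.17e-07 for Ano10. The libraries of both groups did not overlap for 3430 of the 3959 called genes. These were called from the same libraries, so the 3.57% of genes that random groupings give is not a fair comparison.

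Camera called 22 of 40 lists, 19 higher and 3 lower, and 0 with an estimated correlation. Of 20 activated fibroblast markers, 17 were higher, 0 lower and 3 did not pass, and 19 were higher adjusted over the list alone (camera adjusted p = 2.05e-15; adjusted p = 0.262 with an estimated correlation). Of 30 non-collagen matrix proteins, 25 were higher, 1 lower and 4 did not pass. When adjusted over the list alone, 26 were higher and 1 lower (camera adjusted p = 1.68e-16; adjusted p = 0.262 with an estimated correlation), and over all genes 0 were lower without sham replicate 1 or 2 or FG-3149 replicate 2, 3, 4 or 5. Of 19 collagens, 15 were higher, 0 lower and 4 did not pass, and 15 were higher adjusted over the list alone (camera adjusted p = 1.47e-08; adjusted p = 0.334 with an estimated correlation). Of 17 hypertrophy and fetal cardiac genes, 13 were higher, 0 lower and 4 did not pass, and 13 were higher adjusted over the list alone (camera adjusted p = 1.31e-08; adjusted p = 0.262 with an estimated correlation). Of 34 genes of fatty acid oxidation, 0 were higher, 24 lower and 10 did not pass, and 25 were lower adjusted over the list alone (camera adjusted p = 9.33e-12; adjusted p = 0.274 with an estimated correlation). Of 50 genes of oxidative phosphorylation, 1 was higher, 29 lower and 20 did not pass. Adjusted over the list alone, 2 were higher and 31 lower (camera adjusted p = 7.45e-08; adjusted p = 0.504 with an estimated correlation). Over all genes, 0 were higher without sham replicate 1 or 2 or FG-3149 replicate 3 or 4 and 2 without FG-3149 replicate 1, and within the list 0 without sham replicate 1 or 2 and 1 without sham replicate 3 or FG-3149 replicate 3, 4 or 5. Of 13 endothelial markers, 0 were higher, 4 lower and 9 did not pass, and 4 were lower adjusted over the list alone (camera adjusted p = 0.0456; adjusted p = 0.543 with an estimated correlation). They were not called without sham replicate 2 or 3 (camera adjusted p = 0.07 and 0.105, with 2 lower without replicate 3 in both counts), without FG-3149 replicate 1, 2, 3 or 5 (0.0749, 0.0831, 0.0589 and 0.0597) or with the replicate number as a block (0.095), with a lowest value over the refits of 0.0172, and 2 were lower within the list without FG-3149 replicate 1.

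Col1a1 rose 2.07-fold (log2 1.05 ± 0.22 SE), Col3a1 1.78-fold (log2 0.83 ± 0.24 SE) and Tgfb1 1.42-fold (log2 0.51 ± 0.10 SE), and Myh6 fell by 0.28 on the log2 scale (SE 0.07). The edgeR adjusted p was 0.0247 for Col3a1, 0.00143 for Tgfb1 and 0.00545 for Myh6, with ranges over the alternatives of 0.00247 to 0.0882, 0.000123 to 0.0901 and 0.00102 to 0.0505. The call of Col3a1 ended without sham replicate 1, 2 or 3 (adjusted p = 0.0703, 0.0882 and 0.056) and with 1 surrogate variable (adjusted p = 0.0745), that of Myh6 without sham replicate 2 (adjusted p = 0.0505) and that of Tgfb1 with the GC trend removed (log2 0.23; adjusted p = 0.0901) or with GC and length trends removed (adjusted p = 0.0852). The number of called genes was 2477 with 1 surrogate variable. With the GC trend removed it was 3563, and 77.4% of the main calls were kept.

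Both infarcted groups shared 1701 higher and 1479 lower genes against sham, and 0 genes were called in opposite directions. Independent lists of these lengths would share 374 and 296 genes. The correlation of the fold changes across 13434 genes, which are not independent replicates, was 0.938 and their covariance 0.321. In 50 simulated draws without effect, in which both contrasts shared the simulated sham libraries, the averages were 0.639 and 0.0311. The excess is what sharing did not give with genes drawn independently. The 3 real sham libraries were not divided, so a deviation common to them may still add to the excess.

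The fold changes of FG-3149 against IgG were then set beside those of IgG against sham, which share the IgG libraries. Of the 4529 genes called after infarction, 76.2% had the opposite sign with the antibody, as had 63.5% of all tested genes. In 50 simulated draws with no antibody effect the share over called genes was 58.5 ± 0.7% (SD), with a highest value of 60.4%. Genes and libraries were drawn independently, so this SD leaves out genes that change together and structure among the samples. With the IgG libraries divided between both contrasts it was 62.2% to 85.8% over 10 divisions, with a median of 66.4%. The correlation of the fold changes across genes was -0.398, with a covariance of -0.0517, against -0.124 and -0.0134 in the simulated draws. Among 100 splits of the 10 infarcted libraries into groups of 5, 28 gave a share of at least 76.2% in either orientation, the real split included. The median over the other splits was 71.1%.

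**Figure D5:**
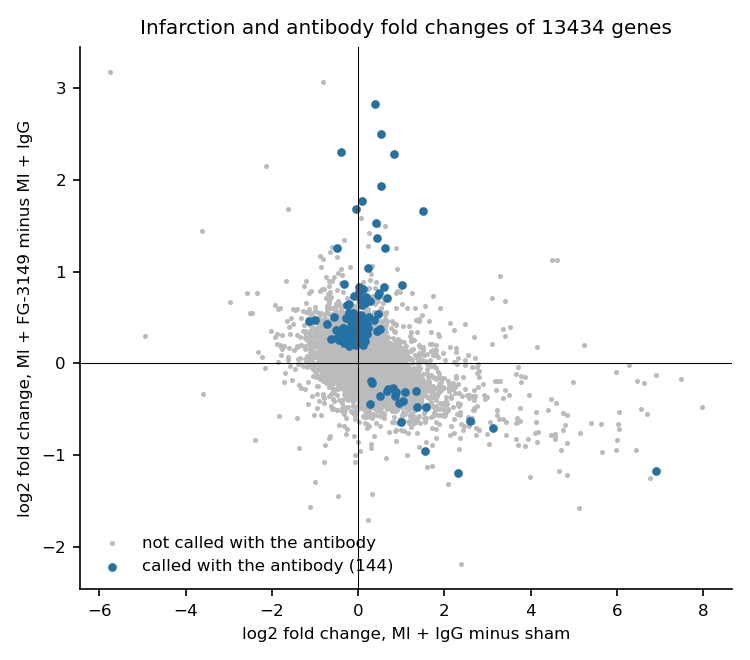
Log2 fold change of FG-3149 against IgG (vertical) plotted against that of IgG against sham (horizontal) for 13434 genes, with the 144 genes called with the antibody in blue and the others in grey. The correlation across genes is -0.398, against -0.124 in simulated draws with no antibody effect, in which genes were drawn independently.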

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

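The tests on genes over and up to 60% GC, the test on the higher calls without IgG replicate 1 and the test on the amount of infarcted tissue were chosen only after the result was seen, as was thinning to a common depth, removal of GC trends and the block of a library split as settings. In the groups of 5 libraries, 168 sets of 5 values were tested for a library apart from the other 4. They held measures of each library and the levels of genes that the rule for naming allowed, of which the text names a part, and 16 had such a library where about 8 are expected by chance. In the IgG group, replicate 1 stood apart for 6 genes. Its level was higher for Acot1 (5.52 CPM against 1.49 to 2.14 in the other 4 libraries), Aldh1l2 (15 against 5.85 to 8.22), Ano10 (48.1 against 29.3 to 34.4) and Kcnv2 (10.6 against 4.34 to 5.45). It was lower for Ankrd1 (3090 CPM against 4470 to 4910) and Ccnd2 (244 against 333 to 348). For all 6 genes IgG replicate 1 lay nearer to sham than the other IgG libraries did. On the first principal component it was at 2.4, the lowest of the infarcted libraries and nearest to sham, against 16.5 to 24.8 in the other IgG libraries. The cause was not tested.

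IgG replicate 2 stood apart as the highest of its group for 6 matrix genes. Without such a gap it was also the highest for other matrix genes, at 837 CPM for Postn (377 to 535 in the other 4), 353 for Cilp (192 to 240) and 105 for Fmod (37.45 to 64.0). For the genes with a gap, its levels were 61.9 CPM for Col12a1 (25.3 to 31.8 in the other 4), 361 for Col1a1 (194 to 227), 871 for Col3a1 (441 to 557) and 201 for Comp (73.9 to 94.0). They were 7.32 CPM for Cthrc1 (2.98 to 3.61) and 209 for Ltbp2 (77.6 to 107). IgG replicate 3 was the lowest of its group for Ifit2, at 29.9 CPM against 33.5 to 33.8. With FG-3149, replicate 3 was the highest for Rps2 (922 CPM against 727 to 781), and replicate 1 was the lowest for Scand1 (14.8 CPM against 24.9 to 28.2) and the highest for Sdha (1840 against 1750 to 1770).

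With FG-3149, 123 genes were higher and 21 lower. Removing each library's GC trend kept 63.9% of the calls and 89.1% of the median log2 fold change of the higher genes, so this trend was not the whole cause. For the 80 higher genes up to 60% GC, 77.5% stayed called and 98.8% of the median was left, which argues against it there. For the 40 over 60% GC, 32.5% stayed called and the median went from 0.44 to 0.29 (64.7% left; median SE 0.08 and 0.07), so GC bias may account for part of those changes and an effect of the antibody on them stays open. Thinning to the smallest total kept 80.6% of the calls, with 5.14 higher calls per lower call, which argues against depth. Without IgG replicate 1 there were 1.82, because lower calls numbered 96 and higher calls 175. Higher genes were then 64.6% of the calls, against 85.4% with that library. This ratio met the outcome set beforehand for that library as a cause, so the excess of higher over lower calls depended on it in part. In the test chosen afterwards, 87.8% of the 123 higher genes stayed called without it (88.2% of all calls), which argues against that library as the source of the higher calls.

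The changes after infarction were on average smaller with FG-3149, with opposite signs for 76.2% of the called genes. Removing the GC trend left 79.6%, which argues against GC trends as the whole cause. Dividing the IgG libraries between the contrasts left at least 62.2% (median 66.4%), so the share did not rest wholly on the shared libraries. No draws without effect were made for divided libraries, so a structure among the samples could still give such shares. However, 28 of 100 splits of the infarcted libraries gave as high a share (highest other 87.0%), so chance could not be excluded. A different amount of infarcted tissue or of surviving muscle in the sampled pieces cannot be told apart from an effect of the antibody: the first principal component differed with p = 0.127 (2-sided exact permutation test), cardiomyocyte markers had a median log2 fold change of 0.06, and no measure of infarct size was used here. An effect of the antibody on the response to infarction therefore remains a hypothesis.

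For IgG against sham, 1 of 56 splits of the libraries called as many genes as the 4529 of the real split. That was the real split itself, and the highest other called 34. For FG-3149 against sham, 1 of 56 splits reached 3959 genes, again the real split, and the highest other called 7. A share of 1 in 56 is the smallest that these splits can give. Each of the other splits put sham and infarcted libraries in the same group, which widens the spread and leaves few calls. Their low counts therefore do not measure chance any further. For FG-3149 against IgG, 2 of 100 splits called at least 144 genes, a small share, with the real split among them. The other called 151, more than the real split, so the number of calls alone cannot exclude chance. That split set IgG replicates 1 and 2 with FG-3149 replicates 1, 2 and 3 against the rest, which points to a structure of the samples across both groups. These 5 libraries lay between -20.5 and -5.6 on the third principal component and the other 5 infarcted libraries between 5.8 and 13.1. The clock gene Arntl was at 13.85 to 18.5 CPM in the first 5 and at 2.46 to 4.82 CPM in the others. Per2 was at 9.83 to 22.6 CPM in the first 5 and at 35.8 to 60.3 CPM in the others, while Dbp overlapped. Sham lay beyond the first 5 for both, at 31.7 to 37.4 CPM for Arntl and 4.93 to 6.7 CPM for Per2. The labels used here gave no batch or time of day, so the source of this structure stays open. For these clock genes, a difference in collection time between sham and infarcted hearts cannot be told apart from infarction. With the split as a block the antibody comparison called 283 genes, 206 higher and 77 lower, and all 144 were among them. The split held libraries of both antibodies and was picked for its number of calls in these same data. This result therefore gives no independent support for the calls.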

How the results depend on the processing

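The settings that removed GC or length trends, thinned the libraries, took a library split as a block or left out IgG replicates 4 and 5 together were chosen only after the result was seen. The count of called genes stayed within 1.5 times of 4529 for IgG against sham in all settings (3329 to 4808 when leaving out a library). For FG-3149 against sham it was 2477 with 1 surrogate variable and otherwise within that range (2641 to 3815 when leaving out a library), against 3959. For FG-3149 against IgG it was 278 with DESeq2, 83 in a fit of only the groups compared and 282 at an adjusted p under 0.1, against 144, and 70 without IgG replicates 4 and 5 together, with 53 of the 144 among them. Leaving out a library gave 68 to 271, with 271 without IgG replicate 1, 68 and 90 without IgG replicates 2 and 5, and 76, 74 and 84 without FG-3149 replicates 3, 4 and 5. The cause was not tested, apart from the smaller number of libraries. Called lists numbered 0 with an estimated correlation in camera for all 3 comparisons, against 22, 14 and 22. By fry they numbered 25 for IgG against sham, 0 for the antibody and 23 for FG-3149 against sham. Fry asks only whether the members of a list moved together, not whether they moved more than other genes. For the antibody, camera called 8 to 18 lists when leaving out a library, with 8 without IgG replicate 2 or FG-3149 replicate 5. Of the list calls, 19 of 22, 6 of 14 and 17 of 22 were kept without each library. The share of genes opposed between both contrasts was 79.6% with the GC trend removed, 63.5% over all tested genes and 72.7% to 82.0% when leaving out a library. With IgG replicate 1 and replicate 3, 4 or 5 in the contrast with sham it was 81.2%, 84.9% and 85.8%, with replicate 2 and replicate 3, 4 or 5 it was 62.2%, 63.0% and 65.8%, and with replicates 3 and 4, 3 and 5 or 4 and 5 it was 66.5%, 63.7% and 66.4%.

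Of the called genes that were followed over all settings, of which the text names a part, 45 of 46 kept their call in every setting for IgG against sham (the exception was Arntl), 10 of 28 for FG-3149 against IgG and 17 of 20 for FG-3149 against sham (the exceptions were Col3a1, Myh6 and Tgfb1). None reversed. Of the genes not called with the antibody, Col1a1 had log2 fold changes of -0.25 to 0.01 when leaving out a library and Col3a1 -0.26 to 0.02, both highest without IgG replicate 2. Tgfb1 had -0.02 to 0.12, lowest without FG-3149 replicate 3, and -0.10 with the GC trend removed and -0.10 with GC and length trends removed. The cause was not tested.

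With the replicate number as a block, 215 genes (169 higher and 46 lower) were called with FG-3149 against IgG, 137 of them shared with the fit without it, and 17 lists. The correlations of the deviations of same-numbered IgG and FG-3149 libraries were 0.18, 0.13, -0.02, 0.02 and 0.06, and only replicate 1 correlated best with its own number. Libraries were not paired by number in the main fit, but these few values cannot exclude a pairing. They also do not exclude a structure across both groups. The split of IgG replicates 1 and 2 with FG-3149 replicates 1, 2 and 3 against the rest pointed to such a structure (151 genes). It set the lower replicate numbers of both groups against the higher ones, and an order by number was not tested. With that split as a block, 283 genes were called (206 higher and 77 lower) with all 144 among them, and 20 lists. Counts with the replicate number as a block were 4139 for IgG against sham and 3576 for FG-3149 against sham. At these depths, the simulated recovery of 76% of 1.5-fold changes between the antibodies limits what a missing call means.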

Other observations

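Further gene lists were counted. For IgG against sham, 13 of 23 oxidative stress response genes were higher, 4 lower and 6 did not pass, with 13 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00218; adjusted p = 0.307 with an estimated correlation). Of 8 genes of class II antigen presentation, 4 were higher, 0 lower and 4 did not pass, and 5 were higher adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.417 with an estimated correlation). In both counts, the number higher was 1 and 2 without sham replicates 1 and 2, 2 without IgG replicate 1, 2 or 3 and 2 with the GC trend removed. The list was not called without IgG replicate 1 (camera adjusted p = 0.0631, the highest over the refits at the preset correlation, from a lowest of 0.000805). The list of 23 adult sarcomere genes was not called. Of its members, 6 were higher, 3 lower and 14 did not pass, with 6 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.563; adjusted p = 0.819 with an estimated correlation).

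Among ribosomal protein genes, 2 of 40 were higher with FG-3149 than with IgG and 38 did not pass, with 3 higher adjusted over the list alone (camera adjusted p = 0.705; adjusted p = 0.931 with an estimated correlation). The number higher was 1 without IgG replicate 2, 4 or 5, and the list was called without FG-3149 replicate 3 (camera adjusted p = 0.0373) and without IgG replicates 4 and 5 together (0.00672, the lowest over the refits, up to 0.971). In the last setting, 6 were lower adjusted over the list alone. Rpl13, of the large subunit, rose 1.27-fold, from 285 ± 14.3 to 361 ± 23.0 CPM (SD, n = 5 each; log2 0.34 ± 0.05 SE; edgeR adjusted p = 0.00299). Hspb1, a small heat shock protein, rose 1.28-fold (log2 0.36 ± 0.06 SE; edgeR adjusted p = 0.00393) and did not pass with GC and length trends removed (log2 0.24; adjusted p = 0.0517).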
